A study of Xenopus laevis with 9 samples.

How the data were processed

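The samples were anterior pieces of wild-type *Xenopus laevis* embryos, cut out at the end of gastrulation (stage 12.5 of Nieuwkoop and Faber) and collected at stage 15 after treatment with 1 µM RA, 10 µM 4-oxo-RA or DMSO, for which the labels also state 10 µM. Per the labels' protocols, RNA was extracted with a spin-column kit and a DNase step, 500 ng of total RNA entered a stranded kit that selects messenger RNA, and cDNA was amplified with 12 PCR cycles. The pooled libraries were sequenced together on 1 lane with paired ends of 50 bases, so the labels give no sequencing batch. Reads were aligned with STAR 2.7.3 per the submitters' processing notes. The counter, the genome build and the annotation were not given in the sources used here, so no coordinates are printed and genes carry the symbols of the deposited table. How reads shared by L and S homeologs or by near-identical copies were counted is likewise unknown, and values of single copies in families such as ventx carry that uncertainty.

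The deposited values were raw counts per gene, whole numbers without normalization, in 1 table of the series and 9 single-sample tables, and each single-sample table equalled its column of the series table. Of 58413 rows, 20906 carried only a LOC identifier, 7111 of all rows a provisional symbol and 11289 a Xelaev identifier, and 0 rows named no gene. Library totals, in units of 10⁶ counts, ranged from 9.40 to 20.9. A count of 0 over a group allows a level of up to 3 counts, 0.0606 CPM in DMSO, 0.0731 in RA and 0.0799 in 4-oxo-RA, and such limits cover counting error only, since PCR copies are not independent molecules.

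Groups and replicate numbers were taken from the sample titles. Replicates of a group differed far beyond sampling noise (chi-square per degree of freedom from 14.3 to 21.6 over genes with at least 20 counts), so no library was a copy of another. Libraries of different treatments with the same replicate number deviated together from their group means (r from 0.434 to 0.536 across genes), while libraries with different numbers did not (r from −0.326 to −0.132), and all 9 libraries were closest to those with their own number. By the rule that every such r exceed 0.1, the numbers pair the samples. The pairing comes from the data, since the labels do not tie a number to a female. The first 3 principal components held 29.3%, 21.6% and 16.8% of the variance.

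The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the counts, with TMM normalization, edgeR's own filter on low counts by group, all 9 libraries in 1 fit and treatment as the only factor. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over 20811 genes. The biological coefficient of variation was 0.272, and 0.138 with the replicate number as a block. CPM were computed with TMM-scaled library sizes.

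A total of 28 gene lists with 573 symbol entries, of which 530 were in the table, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2. A preset correlation between genes of 0.01 and one estimated from the residuals were both used, together with fry, with Benjamini-Hochberg adjustment over the lists. A list needed at least 5 tested genes. Counts called adjusted over the list alone used edgeR p-values adjusted within each list. Symbols were matched with or without the L or S ending, and several lists share members. The lists, the tests, the designs and the rule for naming genes were fixed before the data were examined.

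That rule named, for each comparison, the 5 largest rises and 5 largest falls among called genes with a mean of at least 1 CPM, no overlap between the groups and a real symbol. It added the 3 called members with the smallest adjusted p of each list that passed and 1 of each other list. It always named a fixed set that included cyp26a1, cyp26c1, dhrs3, rara, rarb, rarg, hoxb1, hoxd1, aldh1a2, otx2, six3 and egr2, with L and S copies counted apart. Some genes that the rule names are not reported here. Other genes in the text were chosen after their values were seen.

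The alternatives were RLE normalization, DESeq2 1.42.0, limma-voom, no filter on low counts, a minimum of 10 counts in every library, fits of 2 groups only, the replicate number as a block, each library left out, summed homeologs, an adjusted p below 0.01, and a fold of at least 2. Chance values for the correlation, covariance and shared sign of responses came from 20 simulated pairs of unchanged groups set against the same DMSO libraries. Other settings of the blocked fit, including counts thinned to the smallest library, were added after the data were seen.

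The scripts were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. For RA against DMSO (20049 genes) the unblocked test recovered 22% of genes changed 2-fold and 71% of those changed 4-fold, with 0 false calls, and the blocked test 59% and 89%, with 19 false calls among 167. For 4-oxo-RA against DMSO (20013 genes) the shares were 20% and 70% with 0 false calls, and 58% and 88% with 24 false calls among 170. In the direct comparison (20013 genes) they were 17% and 70% with 0 false calls, and 58% and 86% with 11 false calls among 155. Figures were drawn with matplotlib 3.10.9.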

Results

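Retinoic acid (RA), a vitamin A derivative that binds nuclear receptors, was compared with 4-oxo-RA, which carries an added oxo group on carbon 4 of its ring. The study examined which genes respond to each retinoid in anterior tissue of neurulating *Xenopus laevis* embryos. Anterior pieces were cut from embryos of 3 females at NF stage 12.5, the end of gastrulation. They were kept until NF stage 15, the early neurula, in 1 µM RA, 10 µM 4-oxo-RA or the solvent dimethyl sulphoxide (DMSO). Messenger RNA was sequenced from 9 samples, 3 per treatment. *X. laevis* is allotetraploid, and many genes exist as an L and an S copy (homeologs), which were counted and tested apart.

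Library depth varied within each treatment. Total counts over genes, in units of 10⁶, were 9.40, 20.9 and 18.3 in the DMSO libraries (mean 16.2 ± 6.01, SD, n = 3). They were 11.1, 16.2 and 14.2 with RA (13.8 ± 2.57) and 9.77, 12.36 and 15.9 with 4-oxo-RA (12.7 ± 3.07). The 10 most abundant genes took between 6.23% and 7.19% of the counts in each library. Of 58413 genes in the table, 20811 had enough counts to be tested. Expression is given as counts per 10⁶ counts (CPM) with SD over 3 libraries, and fold changes as log2 values with SE. The labels do not say whether the samples of a treatment came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Libraries with the same replicate number in different treatments resembled one another, and values from a fit with that number as a block stand beside a result where they changed a call or moved a count by more than 1.5 times. Fits with single libraries left out had no block. With all libraries, the block kept every call against DMSO that was made without it.

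RA strongly raised genes whose products break down RA or limit its synthesis. Expression of cyp26a1.S, which encodes a cytochrome P450 that oxidises RA, was 15.3 ± 3.28 CPM in DMSO and 1152 ± 150.2 CPM in RA, a log2 fold change of 6.24 ± 0.18 (edgeR adjusted p = 4.39e-08, n = 3 per group). Its homeolog cyp26a1.L rose by 5.91 ± 0.24 (edgeR adjusted p = 8.89e-07). The retinaldehyde reductase gene dhrs3.L went from 35.1 ± 11.4 to 1079 ± 115 CPM, a change of 4.95 ± 0.25 (edgeR adjusted p = 5.06e-06). The related P450 genes cyp26b1.L, cyp26c1.L and cyp26c1.S rose by 6.89 ± 0.55, 2.73 ± 0.48 and 2.43 ± 0.18. The fold of cyp26b1.L rests on few counts, since the 3 DMSO libraries held 4 between them, and cyp26c1.L missed the threshold when DMSO replicate 2 was left out (edgeR adjusted p = 0.0770). In the list of retinoid metabolism and binding genes, 7 of 20 tested members rose and 13 did not pass, while 11 rose and 3 fell when adjusted over the list alone. In the blocked fit, which has the replicate number as a factor, 12 members rose and 3 fell. Those gained included aldh1a2.L and aldh1a2.S, copies of a gene for an RA-synthesising dehydrogenase, at −1.37 and −1.06 (blocked edgeR adjusted p = 2.60e-04 and 0.00739), and dhrs3.S at 2.81 (blocked edgeR adjusted p = 0.00779). Without the block their values were −1.29 ± 0.33, −1.12 ± 0.44 and 2.75 ± 0.77, with edgeR adjusted p of 0.104, 0.415 and 0.147. As a set the list was higher than other genes (camera adjusted p = 1.64e-09).

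Among 16 tested genes for retinoid receptors and their coregulators, 2 rose, and 3 did when adjusted over the list alone. The receptor gene rara.L rose by 1.70 ± 0.14 (edgeR adjusted p = 1.15e-04) and nrip1.S, which encodes a coregulator of nuclear receptors, by 0.98 ± 0.15 (edgeR adjusted p = 0.00823). The call of nrip1.S was lost without DMSO replicate 2 (edgeR adjusted p = 0.0529). The most abundant receptor gene named beforehand, rarg.S, was at 144 ± 16.9 CPM in DMSO and 142 ± 15.3 CPM in RA, a log2 change of −0.01 ± 0.13. Values for rarb.L and rarg.L were 0.80 ± 0.54 and −1.05 ± 0.43, and neither passed (edgeR adjusted p = 0.791 and 0.451). The copies rara.S, rarb.S and six3.S were not tested, having at most 7, 9 and 0 counts in any library. The 0 counts of six3.S allow up to 0.0606 CPM over the DMSO group, a limit that covers counting error only. The replicate block gave 4 such genes that rose. The set was higher than other genes (camera adjusted p = 0.00145), but not with an estimated correlation between genes (adjusted p = 0.0502).

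Hox genes formed the most completely raised group. Of 18 tested genes of Hox groups 1 to 5, which pattern the hindbrain and neck region, 16 rose, and all 18 did when adjusted over the list alone. Expression of hoxb1.S went from 14.7 ± 5.46 to 57.9 ± 3.91 CPM, a change of 1.99 ± 0.22 (edgeR adjusted p = 7.32e-04), and hoxd1.L and hoxd1.S rose by 2.37 ± 0.36 and 2.45 ± 0.31. The gene hoxb1.L rose by 1.79 ± 0.38 (edgeR adjusted p = 0.0423), a call that was lost without any one of the 6 libraries except DMSO replicate 1 (edgeR adjusted p from 0.0775 to 0.185). With all libraries and the replicate block hoxb1.L passed at 1.84 (blocked edgeR adjusted p = 7.07e-04). Larger rises belonged to genes that were almost silent in DMSO, with 7.08 ± 0.73 for hoxb5.L and 7.02 ± 0.46 for hoxb5.S. Of 7 tested members of Hox groups 6 to 13, hoxb6.L and hoxb6.S rose, by 6.24 ± 0.72 and 5.28 ± 0.61, and 5 did not pass. Adjusted over the list alone, 6 rose, and with the replicate block 5 did. Over the DMSO group hoxb5.L and hoxb6.S had 5 counts each and hoxb5.S and hoxb6.L had 6, so these folds rest on few counts. Both Hox sets were higher than other genes (camera adjusted p = 8.83e-40 for groups 1 to 5 and 2.43e-11 for groups 6 to 13).

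Hindbrain genes other than Hox genes moved in both directions. The Hox cofactor gene meis3.L, chosen after its value was seen, went from 120.2 ± 20.8 to 476 ± 58.5 CPM, a rise of 1.99 ± 0.14 (edgeR adjusted p = 3.97e-05). In contrast, egr2.L, a marker of rhombomeres 3 and 5, went from 21.5 ± 6.43 to 0.647 ± 0.240 CPM, a change of −5.02 ± 0.47 (edgeR adjusted p = 2.46e-04). In the hindbrain list 6 of 28 genes rose, 5 fell and 17 did not pass, against 8 and 10 when adjusted over the list alone. In the blocked fit 8 rose and 11 fell, and with single libraries left out between 2 and 4 fell. Genes that fell also included epha4.S, wnt8b.S and efnb2.L, at −1.25 ± 0.12, −1.62 ± 0.33 and −0.58 ± 0.11, chosen after their values were seen. Another gene of the list, irx3.L, rose by 0.72 ± 0.16 and lost its call without each library but RA replicate 1 (edgeR adjusted p from 0.0884 to 0.211). As a set the list did not differ from other genes (camera adjusted p = 0.685).

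Some forebrain and midbrain genes fell, though most did not pass without the replicate block. The head regulator otx2.L went from 218 ± 25.04 to 61.95 ± 19.99 CPM, a change of −1.82 ± 0.25 (edgeR adjusted p = 0.00333), and otx2.S changed by −0.97 ± 0.15. Its relative otx1.L changed by −2.44 ± 0.26, the forebrain gene fezf2.L by −1.51 ± 0.17, arx.S by −3.43 ± 0.61 and six3.L, which acts in the forebrain and eye, by −1.02 ± 0.21. Of 38 list members 11 fell, 3 rose and 24 did not pass, and adjusted over the list alone 24 fell and 5 rose. With the replicate block 28 fell and 5 rose, and with single libraries left out between 5 and 18 fell. The 3 members that rose were the signalling genes fgf8.L and fgf8.S, at 0.89 ± 0.13 and 0.74 ± 0.12, chosen after their values were seen, and six6.S, a regulator of eye development, at 1.66 ± 0.30. The calls of arx.S were lost without DMSO replicate 1 or 2 or RA replicate 2 or 3 (edgeR adjusted p from 0.0529 to 0.0906), and those of six3.L without DMSO replicate 1 or 3 or RA replicate 2 or 3 (edgeR adjusted p from 0.0794 to 0.134). That of six6.S was lost without each library but RA replicate 1 (edgeR adjusted p from 0.0550 to 0.0982). With all libraries and the replicate block arx.S and six3.L passed (blocked edgeR adjusted p = 5.09e-05 and 5.78e-05). The set was lower than other genes (camera adjusted p = 1.24e-13), but not with an estimated correlation (adjusted p = 0.125). In the eye field list six6.S rose and six3.L fell among 22 genes, 2 rose and 2 fell when adjusted over the list alone, 5 rose and 5 fell with the replicate block, and the set did not differ (camera adjusted p = 0.685).

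Single members of other ectodermal and axial groups of the head fell too. In the cement gland and hatching gland list 6 of 21 genes fell, 11 did when adjusted over the list alone, 13 did with the replicate block and between 3 and 7 did with single libraries left out. They included dmrta1.S (−2.17 ± 0.29, edgeR adjusted p = 0.00298) and pitx1.L (−0.99 ± 0.14, edgeR adjusted p = 0.00377), while genes for secreted products of these glands, such as ag1.L and xepsin.L, at −0.39 and 0.00, did not pass and were chosen after their values were seen. The neural crest list had 4 genes lower of 29, namely snai2.S (−2.53 ± 0.35), snai2.L (−2.19 ± 0.43), sox9.S (−0.95 ± 0.16) and, chosen after its value was seen, twist1.S (−1.63 ± 0.32). Among crest genes 17 fell and 2 rose adjusted over the list alone, with the replicate block 18 fell and 3 rose, and with single libraries left out between 1 and 12 fell. The call of snai2.L was lost without each library but RA replicate 1 (edgeR adjusted p from 0.0572 to 0.135) and that of sox9.S without DMSO replicate 3, RA replicate 2 or RA replicate 3 (0.0606 to 0.0682). With all libraries and the replicate block snai2.L passed (blocked edgeR adjusted p = 6.94e-05). In the notochord and axial midline list gsc.S (−2.36 ± 0.29), arx.S, nog2.S (−2.07 ± 0.38) and, chosen after its value was seen, gsc.L (−2.40 ± 0.51) fell among 30 genes. Of these, gsc marks the prechordal plate and nog2 encodes an antagonist of bone morphogenetic proteins (BMPs). Adjusted over the list alone 12 fell and 3 rose, with the replicate block 14 fell and 1 rose, and with single libraries left out between 1 and 7 fell. The calls of nog2.S were lost without DMSO replicate 2 or 3 or RA replicate 2 or 3 (edgeR adjusted p from 0.0553 to 0.105). Camera adjusted p for the 3 sets were 8.81e-09, 8.72e-07 and 2.42e-04, and with an estimated correlation the adjusted p were 0.0502, 0.346 and 0.347.

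Neuronal gene sets were lower with few single genes past the threshold. In the primary neurogenesis list edgeR called 0 of 33 genes, with 13 at an unadjusted p below 0.05, while DESeq2 called 5 and limma-voom 1. In this list 10 fell and 1 rose adjusted over the list alone, and with the replicate block 11 fell and 1 rose. The set was lower (camera adjusted p = 8.75e-09), but not with an estimated correlation (adjusted p = 0.342). In the neural progenitor list pou3f1.L fell, by 1.33 ± 0.26 on the log2 scale, and irx3.L rose among 36 genes. In all 6 fell and 3 rose adjusted over the list alone, and with the replicate block 14 fell and 4 rose. The call of pou3f1.L was lost without DMSO replicate 1 or 2 or RA replicate 2 or 3 (edgeR adjusted p from 0.112 to 0.145), and that of irx3.L as given above. The set was lower (camera adjusted p = 2.45e-04), but not with an estimated correlation (adjusted p = 0.440) and not without RA replicate 2 (camera adjusted p = 0.0905).

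Several genes of the pronephros, the embryonic kidney, and of fibroblast growth factor (FGF) signalling rose. In the pronephros and intermediate mesoderm list 9 of 18 genes rose, and 10 rose and 2 fell when adjusted over the list alone, while 11 rose and 2 fell with the replicate block and between 5 and 7 rose with single libraries left out. They included gata3.S, from 81.8 ± 3.48 to 237 ± 26.9 CPM (1.54 ± 0.10, edgeR adjusted p = 3.19e-05). The set was higher (camera adjusted p = 1.37e-10). Among 26 FGF pathway genes 7 rose, and 9 did when adjusted over the list alone, among them the feedback inhibitors dusp6.L (1.87 ± 0.13, edgeR adjusted p = 3.03e-05) and spry2.S (1.37 ± 0.16) and the transcription factor gene etv1.S (1.15 ± 0.13). The set was higher (camera adjusted p = 2.40e-06), but not with an estimated correlation (adjusted p = 0.117). Wnt pathway targets were lower as a set (camera adjusted p = 2.30e-04, and adjusted p = 0.0692 with an estimated correlation). Of 27 genes sp5.L, sp5.S and, chosen after its value was seen, wnt8b.S fell, the sp5 copies by 2.25 ± 0.25 and 2.17 ± 0.31 on the log2 scale, while sfrp2.S, which encodes a secreted Wnt antagonist, rose by 1.90 ± 0.23. Adjusted over the list alone 7 fell and 1 rose, with the replicate block 11 fell, and without single libraries between 2 and 5 fell.

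The remaining lists held smaller or mixed changes. In the list of preplacodal ectoderm and placodes, gata3.S and 3 other genes rose and 4 fell among 32, against 9 and 9 when adjusted over the list alone and 9 and 10 with the replicate block (camera adjusted p = 0.985), and between 0 and 5 fell without single libraries. Chosen after their values were seen were pax8.L, pax8.S and foxi4.2.S, which rose, and hesx1.L, hesx1.S and dlx6.S, which fell. In the epidermis list the BMP-responsive homeobox gene msx2.L fell by 1.37 ± 0.13 (edgeR adjusted p = 3.05e-04), msx1.L and krt70.L also fell and foxa1.L rose among 29 genes, these 3 chosen after their values were seen. Adjusted over that list alone 5 fell and 3 rose, and with the replicate block 8 and 4. The set did not pass with all libraries (camera adjusted p = 0.0945), but did without DMSO replicate 1, DMSO replicate 2 or RA replicate 3 (0.00901 to 0.0377). Multiciliated cell and ionocyte genes were higher as a set (camera adjusted p = 0.0259), but not with an estimated correlation (adjusted p = 0.446), with the replicate block (0.0629), or without DMSO replicate 2 or RA replicate 2 (0.147 to 0.160). Of its 29 genes the ionocyte anion exchanger gene slc4a1.L rose, by 1.11 ± 0.17, 2 rose when adjusted over the list alone and 5 did with the replicate block.

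The cardiac, somite, anterior endoderm, posterior growth zone and blood lists did not pass as sets without the block, although single members changed. The pharyngeal regulator tbx1.S rose by 1.68 ± 0.16 (edgeR adjusted p = 3.05e-04), as did tbx1.L and gata5.L, chosen after their values were seen, among 26 cardiac mesoderm genes (6 higher and 4 lower adjusted over the list alone, 7 and 5 with the replicate block, camera adjusted p = 0.704). The co-repressor gene ripply3.S went from 5.61 ± 1.35 to 103 ± 34.8 CPM, a rise of 4.18 ± 0.38 (edgeR adjusted p = 1.93e-04). In its list of 36 somite and presomitic genes foxc1.L, foxc1.S and mespa.L also rose and pcdh8.2.L fell, these 4 chosen after their values were seen, with 5 higher and 1 lower when adjusted over the list alone and 5 lower with the replicate block. That list had a camera adjusted p of 0.457, of 0.0458 on the lower side with the replicate block (adjusted p = 0.642 with an estimated correlation) and of 0.00229 without RA replicate 1. In the anterior endoderm list 2 genes rose and both otx2 copies fell among 24 genes (3 and 2 adjusted over the list alone, 5 lower with the replicate block, camera adjusted p = 0.685). The posterior growth zone list held both sp5 copies, lower, and both fgf8 copies, higher, among 19 genes (2 higher and 3 lower adjusted over the list alone, 5 lower with the replicate block). Its camera adjusted p was 0.204, and passed without DMSO replicate 2 or RA replicate 3 (0.0240 and 0.0104). In the blood and vasculature list cebpd.S rose by 1.35 ± 0.28 among 19 genes (1 adjusted over the list alone, 2 higher and 1 lower with the replicate block, camera adjusted p = 0.910), a call lost without DMSO replicate 2 or 3 or RA replicate 2 or 3 (edgeR adjusted p from 0.0970 to 0.168).

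Of the Hedgehog targets gli3.L fell, by 1.05 ± 0.14 on the log2 scale, among 16 genes (1 adjusted over the list alone, 1 higher and 2 lower with the replicate block, camera adjusted p = 0.4998). Lists that could reveal general effects of the treatment did not pass either. EdgeR called 0 of 22 Notch pathway genes, 0 of 42 cell cycle genes, 0 of 35 stress and p53 response genes and 0 of 17 xenobiotic response genes, with 8, 3, 3 and 1 at an unadjusted p below 0.05. DESeq2 called 3 of the Notch pathway genes and 0 in the other lists, and limma-voom called 0 in all 4. The blocked fit called 4 Notch genes higher and 3 lower, 3 stress genes higher and 1 lower, and 1 higher and 1 lower in both the cell cycle and the xenobiotic list. Adjusted over each list alone, 4 Notch genes rose and 2 fell and edgeR called 0 in the other 3 lists. Camera adjusted p were 0.685, 0.914, 0.954 and 0.561.

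Counted over all genes, 349 differed between RA and DMSO in edgeR's quasi-likelihood test, 254 higher and 95 lower, of which 192 and 61 changed at least 2-fold. The replicate block raised the count to 1389, 729 higher and 660 lower, including all 349. Among the largest falls were also pnhd.L, which encodes a secreted protein (−3.08 ± 0.32), and crisp1.7.L, of the cysteine-rich secretory protein family (−3.002 ± 0.47). The count was 223, 197 and 204 without DMSO replicates 1, 2 and 3, and 215 and 194 without RA replicates 2 and 3, so it moved by more than 1.5 times with any of these 5 libraries left out. DESeq2 called 636 genes (404 higher and 232 lower), and without a filter on low counts edgeR called 831 (481 higher and 350 lower). No library of one group overlapped the other group for 14.7% of tested genes, a share that would be 10% by chance for exchangeable libraries, which these paired ones are not. Of the 14 lists that passed with camera's preset correlation, the retinoid metabolism, both Hox and the pronephros lists also passed with an estimated correlation (adjusted p from 0.0159 to 0.0274), but not when the replicate block was added to it (0.0626 to 0.0935). In fry, which asks whether a list's genes move one way on balance, 9 lists passed, and with the replicate block also primary neurogenesis (fry adjusted p from 0.134 to 0.0210), neural progenitors (from 0.206 to 0.0161) and axial midline (from 0.117 to 0.0125). In the cardiac, placode and stress lists the median and the camera direction differed in sign, as did the median and mean of the cell cycle list, and none of these passed.

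**Figure D1:**
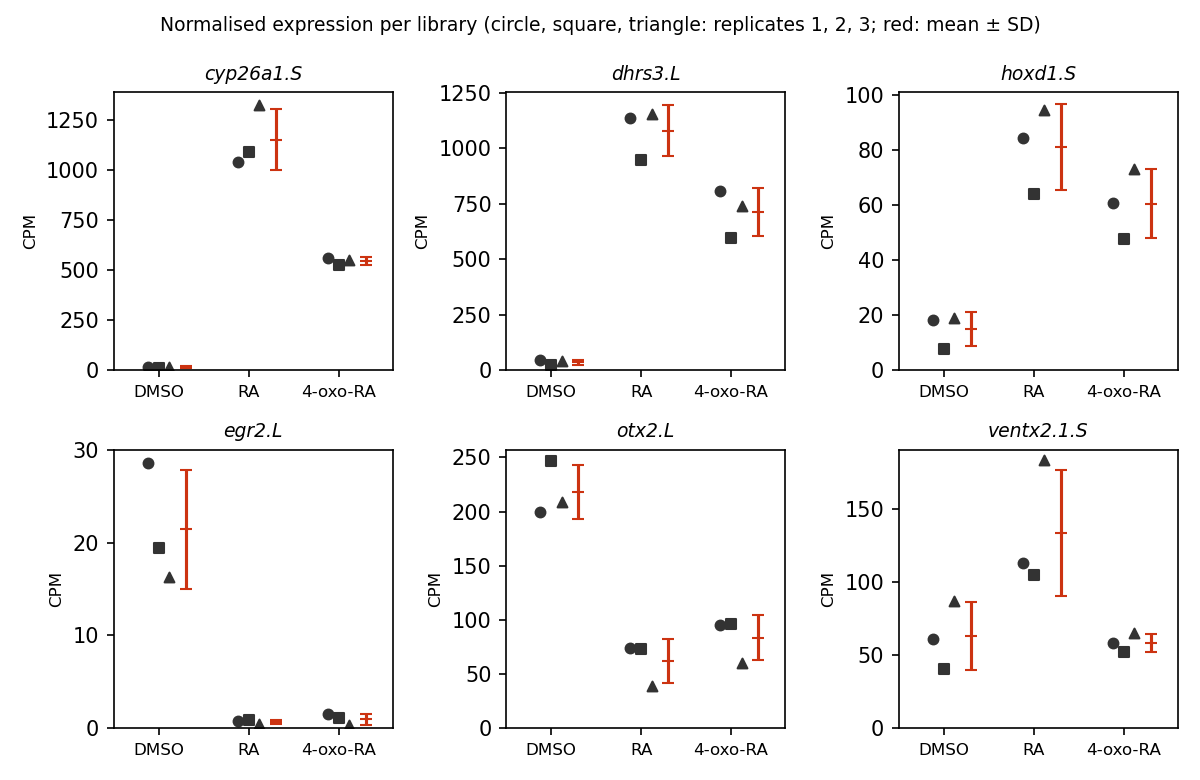
Normalised expression in CPM of 6 genes in each of the 9 libraries, by treatment, with symbols for replicate numbers and the mean and SD of 3 libraries in red. For cyp26a1.S the DMSO libraries averaged 15.3 CPM, the RA libraries 1152 and the 4-oxo-RA libraries 545, while egr2.L averaged 21.5, 0.647 and 0.940.

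The second comparison asked which genes respond to 10 µM 4-oxo-RA, against the same DMSO libraries. 4-oxo-RA raised the same enzymes of RA breakdown that are named above. Expression of cyp26a1.S rose from 15.3 ± 3.28 to 545 ± 19.2 CPM, a log2 fold change of 5.16 ± 0.17 (edgeR adjusted p = 2.06e-07, n = 3 per group), and cyp26a1.L rose by 4.95 ± 0.23. The reductase gene dhrs3.L rose to 713 ± 108 CPM (4.35 ± 0.24, edgeR adjusted p = 1.48e-05), cyp26c1.S by 2.30 ± 0.18 and cyp26c1.L by 2.98 ± 0.48. The call of cyp26c1.L was lost without DMSO replicate 2 or 4-oxo-RA replicate 1 (edgeR adjusted p = 0.0900 and 0.0505). In the retinoid metabolism list 6 of 20 genes rose, against 11 higher and 2 lower when adjusted over the list alone (camera adjusted p = 5.73e-13). In the blocked fit 12 rose and 3 fell, including dhrs3.S at 2.62 and aldh1a2.L and aldh1a2.S at −1.22 and −0.86 (blocked edgeR adjusted p = 0.0242, 0.00124 and 0.0452). Without it their values were 2.84 ± 0.77, −1.21 ± 0.33 and −0.83 ± 0.44, with edgeR adjusted p of 0.230, 0.233 and 0.935. Of 16 receptor and coregulator genes rara.L rose, by 1.29 ± 0.14 (edgeR adjusted p = 0.00153), 3 rose when adjusted over the list alone and 4 with the replicate block (camera adjusted p = 1.37e-04). Values of rarb.L, rarg.L and rarg.S were 0.32 ± 0.55, 0.29 ± 0.41 and −0.00 ± 0.13.

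Hox genes rose here as well. Of the genes of groups 1 to 5, 12 of 18 rose and all 18 did when adjusted over the list alone (camera adjusted p = 1.49e-38). Examples were hoxb1.S (1.68 ± 0.22, edgeR adjusted p = 0.00452), hoxd1.L (2.15 ± 0.36), hoxd1.S (2.03 ± 0.31) and hoxd4.L, from 1.31 ± 1.11 to 46.4 ± 20.8 CPM (5.25 ± 0.64). The nearly silent hoxb5.L and hoxb5.S rose by 5.68 ± 0.74 and 5.31 ± 0.47. The gene hoxb1.L, at 1.05 ± 0.38, did not pass (edgeR adjusted p = 0.523), but did with the replicate block at 1.15 (0.0447). Of 7 genes of groups 6 to 13, hoxb6.L and hoxb6.S rose, by 5.097 ± 0.72 and 3.47 ± 0.63, and 4 did when adjusted over the list alone (camera adjusted p = 5.89e-08). Without single libraries the call of hoxd1.L was lost for DMSO replicate 1 and 4-oxo-RA replicates 1 and 3 (edgeR adjusted p from 0.0722 to 0.0925), that of hoxd1.S for 4-oxo-RA replicate 3 (0.0537) and that of hoxb6.S for all but 4-oxo-RA replicate 1 (0.0610 to 0.170). In the hindbrain list 5 of 28 genes rose and 2 fell, as 5 and 5 did when adjusted over the list alone (camera adjusted p = 0.673). They included meis3.L (1.77 ± 0.14, edgeR adjusted p = 2.16e-04), while egr2.L went to 0.940 ± 0.574 CPM (−4.57 ± 0.46, edgeR adjusted p = 8.61e-04) and epha4.S, chosen after its value was seen, to −0.78 ± 0.12. In the blocked fit 4 hindbrain genes fell, and without single libraries 1 or 2.

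Some head genes fell with 4-oxo-RA too. In the forebrain and midbrain list otx1.L (−1.60 ± 0.25, edgeR adjusted p = 0.0119), otx2.L (−1.39 ± 0.25, edgeR adjusted p = 0.0286) and, chosen after its value was seen, fezf2.L (−0.96 ± 0.17) fell among 38 genes, and fgf8.L (0.98 ± 0.13) and fgf8.S (0.85 ± 0.12) rose. In that list 16 fell and 3 rose adjusted over the list alone, with the replicate block 19 fell and 4 rose, and with single libraries left out at most 1 fell. The call of otx2.L was lost without any one of the 6 libraries (edgeR adjusted p from 0.0652 to 0.122) and that of otx1.L without DMSO replicate 2 or 4-oxo-RA replicate 2 or 3 (0.0513 to 0.0702). With all libraries and the replicate block otx2.L and otx1.L passed (blocked edgeR adjusted p = 1.25e-05 and 1.61e-05). Both otx2.S, at −0.70 ± 0.15, and six3.L, at −0.55 ± 0.21, did not pass (edgeR adjusted p = 0.0904 and 0.567), but did with the replicate block at −0.71 and −0.56 (0.00304 and 0.0146). In the cement gland list 1 of 21 genes fell, 6 did adjusted over the list alone and 7 with the replicate block. The crest gene snai2.S changed by −1.75 ± 0.33 (1 of 29 lower, 4 adjusted over the list alone, 9 lower and 3 higher with the block) and the prechordal gene gsc.S by −1.67 ± 0.28 (1 of 30 axial genes lower, 6 lower and 2 higher adjusted over the list alone, 11 lower with the block). The calls of snai2.S and gsc.S were lost without any one of the 6 libraries (edgeR adjusted p from 0.0648 to 0.209 and from 0.0549 to 0.126). These 4 sets were lower than other genes, with camera adjusted p of 1.18e-09, 2.38e-07, 1.23e-04 and 0.00504 in that order. With an estimated correlation the adjusted p were 0.229, 0.0754, 0.509 and 0.509, and the axial set missed the threshold without DMSO replicate 1, DMSO replicate 3 or 4-oxo-RA replicate 2 (camera adjusted p from 0.0852 to 0.280).

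A few epidermal genes fell, among them feedback components of BMP signalling. Of 29 genes msx2.L (−1.10 ± 0.13, edgeR adjusted p = 0.00289), msx1.L (−0.82 ± 0.16), szl.S (−1.09 ± 0.20) and, chosen after its value was seen, szl.L (−1.26 ± 0.24) fell, where szl encodes sizzled, a secreted inhibitor in the BMP pathway. Adjusted over the list alone 7 fell and 1 rose, with the replicate block 10 fell and 1 rose, and without single libraries between 1 and 3 fell. The call of szl.S was lost without each library but 4-oxo-RA replicate 2 (edgeR adjusted p from 0.0784 to 0.142) and that of msx1.L without any one of the 6 (0.0549 to 0.182). With all libraries and the replicate block szl.S and msx1.L passed (blocked edgeR adjusted p = 0.00178 and 5.22e-04). The set was lower (camera adjusted p = 4.50e-05), but not with an estimated correlation (adjusted p = 0.258). Pronephric genes rose, 6 of 18, and 9 did when adjusted over the list alone (camera adjusted p = 3.94e-09), including gata3.S at 1.14 ± 0.10 (edgeR adjusted p = 4.35e-04). The replicate block gave 9 that rose, and without single libraries between 3 and 5. Of the FGF pathway genes 7 of 26 rose, and 10 rose and 1 fell both adjusted over the list alone and with the replicate block, including dusp6.L (1.55 ± 0.12) and etv1.S (0.96 ± 0.13), with a camera adjusted p of 5.16e-08 and an adjusted p of 0.0754 with an estimated correlation. Of 27 Wnt targets sfrp2.S rose, by 1.51 ± 0.23, and sp5.L fell, by 1.51 ± 0.24 on the log2 scale, while 1 rose and 4 fell when adjusted over the list alone and 5 fell with the replicate block (camera adjusted p = 0.00504, and adjusted p = 0.159 with an estimated correlation). The call of sp5.L was lost without DMSO replicate 2 or 3 or 4-oxo-RA replicate 1 or 3 (edgeR adjusted p from 0.0577 to 0.0873). The primary neurogenesis set was lower (camera adjusted p = 3.66e-05, and adjusted p = 0.509 with an estimated correlation), although edgeR called 0 of its 33 genes over all genes and 0 adjusted over the list alone, with 7 at an unadjusted p below 0.05, 2 called by DESeq2, 0 by limma-voom, and 4 lower and 1 higher with the replicate block.

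The other 15 lists did not pass for 4-oxo-RA (camera adjusted p from 0.106 to 0.965). Their named members included ripply3.S (3.23 ± 0.37, edgeR adjusted p = 0.00186) and tbx1.S (1.25 ± 0.16, edgeR adjusted p = 0.00449), which rose, and gli3.L (−0.95 ± 0.14, edgeR adjusted p = 0.0101), which fell. Among these lists 4 placode, 2 cardiac, 2 somite, 2 endoderm and 2 posterior growth zone genes rose and 3 posterior growth zone genes and 1 endoderm gene fell, against 6, 3, 3, 2 and 2 higher and 4, 3, 1, 3 and 4 lower in the order placodes, cardiac, somite, endoderm and posterior growth zone when adjusted over the list alone. Without single libraries between 1 and 4 placode genes and 1 or 2 cardiac and somite genes rose. Between 0 and 3 posterior growth zone genes and 0 endoderm genes fell. EdgeR called 0 genes in the eye field, neural progenitor, blood, Notch, cell cycle, stress and xenobiotic lists, over all genes or adjusted over the list alone, with 4, 6, 1, 6, 2, 2 and 1 at an unadjusted p below 0.05 and 0 called by DESeq2 or limma-voom. The blocked fit called 2 eye field genes higher and 3 lower, 2 neural progenitor genes higher and 1 lower, 1 blood gene higher and 1 lower, 3 Notch genes and 1 cell cycle gene higher, and 0 in the stress and xenobiotic lists. In that fit 7 placode genes rose and 6 fell, 4 cardiac genes rose and 6 fell, 3 somite genes rose and 1 fell, 5 endoderm genes fell, and 1 Hedgehog gene rose and 2 fell. The ionocyte gene slc4a1.L rose by 0.91 ± 0.17 (edgeR adjusted p = 0.0383), a call lost without each library but 4-oxo-RA replicate 3 (0.0866 to 0.216). That of gli3.L was lost without DMSO replicate 2 or 4-oxo-RA replicate 3 (edgeR adjusted p = 0.0565 and 0.0604). With single libraries left out, camera adjusted p below the threshold arose for the posterior growth zone list (0.00227 to 0.0488 without DMSO replicate 1 or 2 or 4-oxo-RA replicate 1 or 3) and the Notch list (0.0107 and 0.0223 without DMSO replicate 1 or 4-oxo-RA replicate 2). The same held for the somite list (0.0239 without DMSO replicate 1) and the eye field list (0.0222 without 4-oxo-RA replicate 1). The hindbrain, placode and somite lists had medians opposite in sign to the camera direction, and in the stress list the median and the mean differed in sign.

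Counted over all genes, 153 differed between 4-oxo-RA and DMSO in edgeR's quasi-likelihood test, 130 higher and 23 lower, of which 103 and 19 changed at least 2-fold. The largest falls besides egr2.L were those of crisp1.7.L (−2.60 ± 0.46), the craniofacial homeobox gene alx1.L (−2.31 ± 0.31) and pnhd.L (−1.94 ± 0.31). The call of crisp1.7.L was lost without any one of the 6 libraries (edgeR adjusted p from 0.0577 to 0.158) and that of pnhd.L without DMSO replicate 2 or 3 or 4-oxo-RA replicate 2 or 3 (0.0551 to 0.0873). With all libraries and the replicate block crisp1.7.L passed (blocked edgeR adjusted p = 1.61e-05). The replicate block raised the count to 700, 427 higher and 273 lower, including all 153. The count was 97, 75 and 90 without DMSO replicates 1, 2 and 3 and 94 without 4-oxo-RA replicate 3. DESeq2 called 324 genes (241 higher and 83 lower), and edgeR without a filter on low counts called 453 (294 higher and 159 lower). No library of one group overlapped the other for 11.2% of genes. With an estimated correlation 5 of the 13 lists passed, namely retinoid metabolism, receptors, both Hox lists and pronephros (adjusted p from 0.0148 to 0.0425), but not when the replicate block was added to it (0.0528 to 0.228), and 7 lists passed in fry, joined with the block by the forebrain and midbrain list (fry adjusted p from 0.112 to 0.0457).

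**Figure D2:**
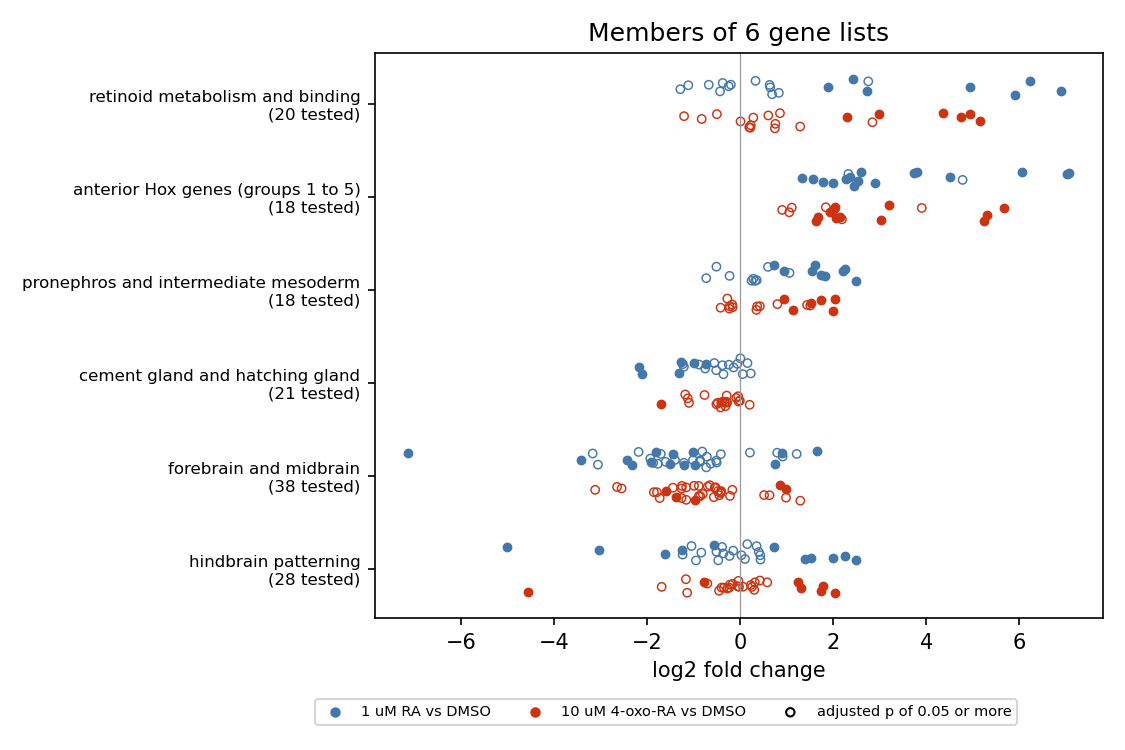
Log2 fold change against DMSO of every tested member of 6 gene lists, 1 point per gene, for 1 µM RA (blue) and 10 µM 4-oxo-RA (red), filled where the edgeR adjusted p was under 0.05. Of the 18 anterior Hox genes 16 rose with RA and 12 with 4-oxo-RA, and of the 38 forebrain and midbrain genes 11 and 3 fell.

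The third comparison set 4-oxo-RA directly against RA, at 10 µM and 1 µM, so it compares these treatments and not the compounds at a matched dose. Some genes that RA raised stood lower with 4-oxo-RA once replicate numbers were taken into account. The replicate block put cyp26a1.S at 545 against 1152 CPM, a log2 difference of −1.08 ± 0.10 (blocked edgeR adjusted p = 1.48e-04, 95% interval −1.28 to −0.87), and cyp26a1.L at −0.94 ± 0.10 (8.73e-04). In the same fit dhrs3.L differed by −0.61 ± 0.10 (blocked edgeR adjusted p = 0.0233). Without the block the edgeR adjusted p was 0.286 for cyp26a1.S and 1.000 for cyp26a1.L and dhrs3.L. For rara.L the difference was −0.41 ± 0.14, for cyp26c1.S −0.13 ± 0.17, for otx2.L 0.43 ± 0.24, for egr2.L 0.45 ± 0.53 and for rarg.S 0.01 ± 0.13. Their 95% intervals ran from −0.71 to −0.11, from −0.50 to 0.24, from −0.11 to 0.97, from −0.71 to 1.61 and from −0.26 to 0.29, and none of these genes passed with or without the block. Nor did cyp26c1.L (0.25 ± 0.44), dhrs3.S (0.09 ± 0.67), aldh1a2.L (0.08 ± 0.33), aldh1a2.S (0.29 ± 0.44), hoxb1.L (−0.73 ± 0.36), hoxb1.S (−0.31 ± 0.21), hoxd1.L (−0.22 ± 0.34), hoxd1.S (−0.42 ± 0.29), otx2.S (0.27 ± 0.15), six3.L (0.47 ± 0.21), rarb.L (−0.48 ± 0.54) or rarg.L (1.34 ± 0.43).

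Over all genes edgeR's quasi-likelihood test called 0 of 20811 in the direct comparison, with 532 at an unadjusted p below 0.05. DESeq2 called 13, limma-voom 1 and edgeR without a low-count filter 46, and no library of one group overlapped the other for 6.48% of genes. With the replicate block edgeR called 33 genes, 5 higher and 28 lower with 4-oxo-RA, and 1600 had an unadjusted p below 0.05. Of these 33, 30 were also called between RA and DMSO in that fit and all 33 differed in the direction opposite to their RA response, toward which the RA libraries that both comparisons share pull by themselves. Higher genes, chosen after their values were seen, included the neural genes hes3.S, nes.L and epha4.S, at 0.91, 0.69 and 0.48. The 28 lower genes included cyp26b1.L, hoxb4.S, hoxb5.L, hoxb5.S, hoxc5.L and ripply3.S, chosen likewise, at −2.15, −1.48, −1.36, −1.70, −1.64 and −0.97. Without replicate set 1, 2 or 3 the blocked count was 102, 23 or 9, of which 22, 17 and 6 were among the 33. The balance of directions depended on the setting, with 69 higher and 33 lower without replicate set 1, 91 and 95 with blocked DESeq2 and 161 and 128 in the blocked fit without a low-count filter. For 60.2% of tested genes the 95% interval of the difference lay within 2-fold in either direction, and for 68.5% with the block.

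Gene lists gave the same picture with camera's preset correlation only. Both Hox lists were lower with 4-oxo-RA than with RA (camera adjusted p = 9.00e-14 for groups 1 to 5 and 8.14e-06 for groups 6 to 13), with list medians of −0.63 and −1.15, as were the pronephros (0.00456), cardiac (0.0391), multiciliated (2.72e-04) and epidermis (0.0348) lists. Higher lists were forebrain and midbrain (1.01e-06, median 0.31), neural progenitors (1.59e-06), neural crest (0.00161), primary neurogenesis (0.00240), cement gland (0.00960), Wnt targets (0.0268) and axial midline (0.0272). With an estimated correlation between genes 0 of these 13 lists passed (lowest adjusted p = 0.211), and in fry 0 did (lowest 0.173). Over the lists alone edgeR called 7 anterior Hox, 2 posterior Hox, 3 retinoid metabolism, 2 pronephros, 2 epidermis, 2 eye field and 1 posterior growth zone genes, all lower, and over all genes it called 0 in every list. The blocked fit called 6 anterior Hox, 4 retinoid metabolism and 1 each of eye field, epidermis, cardiac and somite genes lower, and 1 each of hindbrain and neural progenitor genes higher. Only the lists of anterior Hox and pronephros genes passed whichever library was left out. The posterior Hox list was lost without RA replicate 3 or 4-oxo-RA replicate 1 or 2, and the forebrain list without RA replicate 3 (camera adjusted p from 0.0645 to 0.0990, and 0.0531). Neural progenitors were lost without RA replicate 2 (0.0588), multiciliated cells without 4-oxo-RA replicate 3 (0.0959) and cardiac genes without any one of the 6 (0.0665 to 0.182). Neural crest, primary neurogenesis, cement gland and axial midline lists were lost without RA replicate 2, RA replicate 3 or 4-oxo-RA replicate 1 (camera adjusted p from 0.0707 to 0.554). Wnt targets were lost without each library but RA replicate 1 (0.0530 to 0.261) and epidermis without each but RA replicates 1 and 2 (0.0544 to 0.371). The somite list, at 0.130, passed on the higher side with the replicate block (0.0175, but adjusted p = 0.507 with an estimated correlation) and without RA replicate 1 (4.91e-05). Without RA replicate 1 the hindbrain (0.0433), Hedgehog (0.00907) and Notch (0.00178) lists also passed, as did retinoid metabolism without it or 4-oxo-RA replicate 3 (0.0412 and 0.00576) and cell cycle without RA replicate 3 (0.00741). The lists that did not pass had camera adjusted p from 0.0760 to 0.941, and among them the median, mean and camera direction differed in sign for retinoid metabolism, receptors, eye field, posterior growth zone, FGF, stress and xenobiotic genes.

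The responses to both retinoids were set side by side across genes, which are not independent replicates. Of the genes called for each, 129 rose with both and 20 fell with both, 149 in all, and no gene was called in opposite directions, while with the replicate block ventx2.2.S was (0.40 with RA and −0.41 with 4-oxo-RA, blocked edgeR adjusted p = 0.0314 and 0.0479). Independent lists of these sizes would share 1.59 and 0.105 genes. In 20 simulations of unchanged groups against the same DMSO libraries edgeR called 0 genes for either group, so these give no chance value for the overlap. Part of the excess may come from the shared DMSO libraries, which are too few to be split. With the replicate block, where the simulated groups had 1.8 and 1.35 calls on average and shared 0.15 (at most 1), 393 and 230 genes were shared, against 15.0 and 8.66 for independent lists, and without DMSO replicates 1, 2 and 3 or 4-oxo-RA replicate 3 the count of 149 became 95, 73, 88 and 93. Log2 fold changes of all tested genes correlated with Pearson r = 0.754 and Spearman rho = 0.621, against a mean r of 0.488 in the simulations, and had a covariance of 0.209 against 0.0499. They had the same sign for 72.9% of genes, against 66.3% in the simulations. Without the block 4 genes were called for 4-oxo-RA and not for RA, szl.L, szl.S, egr4.L and MGC131011, the last 2 and szl.L chosen after their values were seen. For none of them did the direct test pass (blocked edgeR adjusted p = 0.392, 0.0932, 0.119 and 0.794). In the blocked fit 34 higher and 43 lower genes were called for 4-oxo-RA and not for RA in the same direction, with ventx2.2.S among the 43. In that fit szl.L, egr4.L and MGC131011 were called for RA too (blocked edgeR adjusted p = 0.0399, 0.0383 and 0.00365).

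Among the 624 genes that the blocked fit called for both retinoids, the median ratio of the 4-oxo-RA log2 fold change to that of RA was 0.818, and 515 had the smaller change with 4-oxo-RA. Fitted within each replicate number, the slope of the 4-oxo-RA on the RA response averaged 0.786 ± 0.0173 (SD, n = 3). For the 18 anterior Hox genes the slope was 0.753 ± 0.0704, and all 18 had the smaller change with 4-oxo-RA. The median ratio depended on how genes were picked, at 0.708 over the 1389 genes called for RA in the blocked fit. Over the 700 genes called for 4-oxo-RA it was 0.848. The doses differed, and these ratios hold for these doses only.

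**Figure D3:**
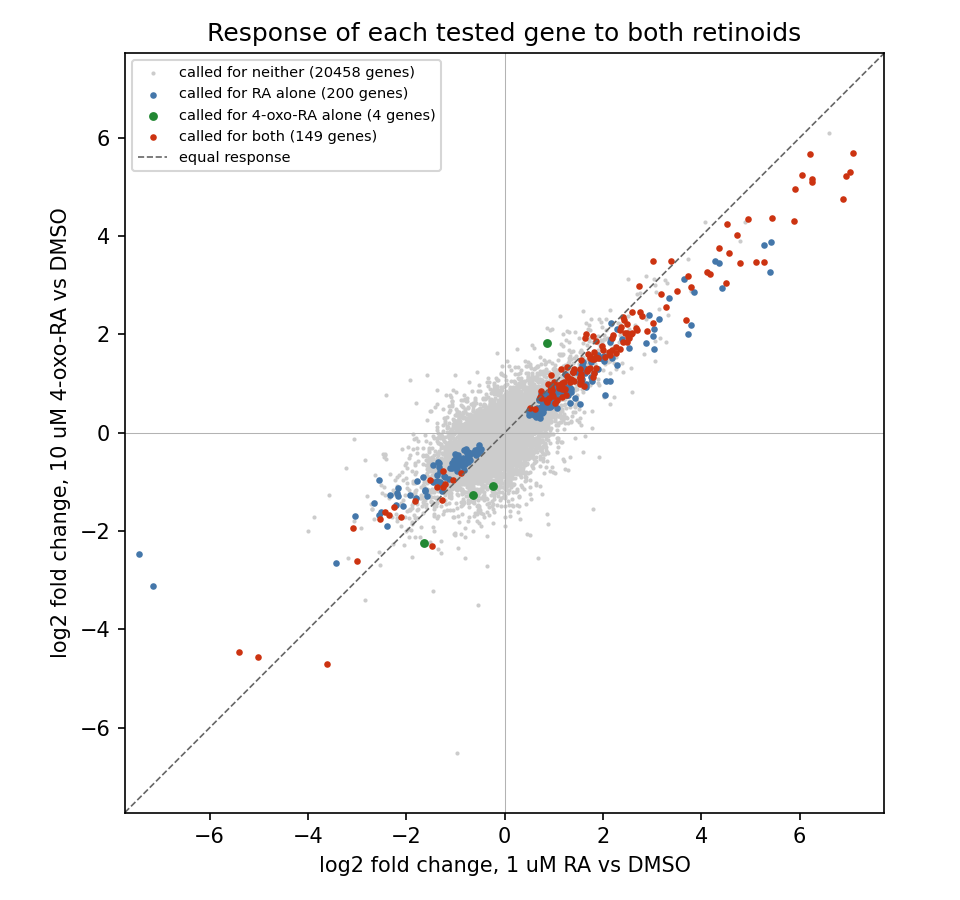
Log2 fold change against DMSO of each of the 20811 tested genes with 1 µM RA (horizontal) and 10 µM 4-oxo-RA (vertical), coloured by the comparisons in which edgeR called it. Of the 149 genes called for both (red), 132 had the smaller change with 4-oxo-RA, measured from 0, and the dashed line marks equal responses.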

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

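For the smaller response to 4-oxo-RA, the tests on genes picked by 4-oxo-RA values, on library depth and on a single scaled response were chosen only after the result was seen. What drew attention was a difference between groups, since with the replicate block 33 genes differed between the RA and the 4-oxo-RA libraries. Picking genes by their 4-oxo-RA calls left a mean slope of 0.795 (1 would mean equal size), and 515 of these 700 genes had the smaller change with 4-oxo-RA. All 515 were among the 624 of the 700 that were called for RA too, and no gene called for 4-oxo-RA alone had the smaller change. The slope below 1 argues against genes picked by their RA values as the whole cause. The picks share most genes and are not independent, so a part played by such picking stays open. Thinning all libraries to 1 depth left a median ratio of 0.820. It was a weak test of unequal library depth, since thinning does not shift expected fold changes. After the RA response was scaled by the common ratio, 2 of the 33 genes still differed, as one response at a smaller size allows for the other 31. Outside the 33, cyp26c1.L stood above the scaled response by 0.75 ± 0.10 (blocked edgeR adjusted p = 0.0127), at 2.78 with RA and 3.03 with 4-oxo-RA. Its homeolog cyp26c1.S, at 2.42 and 2.28, was not called. In all 3 genes were called beyond scaling, the others being ventx2.1.S and ventx2.2.S. In 1 simulated draw, genes called for RA kept their RA response, 4-oxo-RA had 0.8 of it, and other genes had no response. That draw also gave 3 such calls, with a recovered ratio of 0.832. A count of 3 is therefore by itself no sign of more than one scaled response. A single draw does not tell whether cyp26c1.L and the ventx2 genes follow one. Dose and compound changed together here, so the smaller size may belong to either.

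For the ventx2 genes all 3 tests were chosen only after the result was seen. These homeobox genes, which act downstream of BMP signalling in ventral tissue, were picked out by a difference between groups that the direct test with the replicate block found, with log2 values for 4-oxo-RA minus RA of −1.16 ± 0.13 for ventx2.1.S and −0.81 ± 0.11 for ventx2.2.S (blocked edgeR adjusted p = 9.52e-04 and 0.00460). Expression of ventx2.1.S was 63.0 ± 23.3 CPM in DMSO, 134 ± 43.3 in RA and 58.3 ± 6.41 in 4-oxo-RA, and ventx2.2.S was the only gene called in opposite directions with the block, at 0.40 with RA and −0.41 with 4-oxo-RA (blocked edgeR adjusted p = 0.0314 and 0.0479). Summed over 8 copies of the family the difference beyond the scaled RA response was −0.73 ± 0.10, which argues against reads moved between ventx copies. The median over 73 posterior, somite and blood genes was 0.0564 (0.0295, 0.302 and 0.0336 for the lists apart), against −0.96 for ventx2.1.S. That argues against a gain of such tissue in the RA explants as large as the ventx2.1.S difference. A smaller gain, or a gain of epidermis, was not tested. Lower BMP target expression could contribute. A list of 30 BMP pathway genes, which held other ventx copies and genes whose values had been seen, had 24 lower. Of the 30, 10 were lower and 0 higher at an unadjusted p below 0.05. It gave a camera p of 4.14e-06 with the preset and 0.189 with an estimated correlation. Its 11 members outside the other lists and the ventx family gave a camera p of 0.0146 with the preset and 0.306 with an estimated correlation, which leaves it open.

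For the counts of differing genes, the splits of the libraries were set before the result was seen and no test was chosen after it. With 3 libraries against 3 the splits are too few for a share below 0.05. For RA against DMSO 1 of 10 splits reached the 349 genes of the real grouping and 1 of 4 with the block reached 1389, and the highest other split gave 0 in both. For 4-oxo-RA against DMSO 1 of 10 splits reached 153 and 1 of 4 reached 700, with 0 as the highest other. For 4-oxo-RA against RA all 10 of 10 splits gave as many as the real 0, while with the block 1 of 4 splits reached 33 and the highest other gave 0.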

How the results depend on the processing

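RLE normalization, fits of 2 groups, a minimum of 10 counts, summed homeologs and a fold of at least 2 kept each count of differing genes within 1.5 times. Named genes were recomputed with RLE normalization, DESeq2, no low-count filter, fits of 2 groups, the replicate block and left-out libraries only. Of 133 results 91 kept their call under all of these and none reversed. Among 1463 such values DESeq2 gained 7 calls, the fit without a low-count filter 10 and the replicate block 14, fits of 2 groups lost 8 and gained 2, and left-out libraries lost 114 and gained 2. Among the named genes and gene set tests reported here the replicate block changed no other call than those given above. Of simulated 2-fold changes in the direct comparison 17% were recovered without the block and 58% with it. False calls numbered 0 without the block and 11 among 155 calls with it. Thinning to the smallest library moved the blocked count from 33 to 29.

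For RA against DMSO, 4-oxo-RA against DMSO and the direct comparison, in that order, DESeq2 gave 636, 324 and 13 genes, no low-count filter 831, 453 and 46, and the replicate block 1389, 700 and 33. The cause was not tested. An adjusted p below 0.01 left 161 and 78 genes by construction, and limma-voom gave 1 gene in the direct comparison. Without single libraries the counts ran from 194 to 366 and from 75 to 112. Genes called for both retinoids in the same direction, 149 in the main test, numbered 407 without a filter, 623 with the replicate block and 73 to 144 without single libraries. The correlation of fold changes, 0.754, became 0.519 without a filter, 0.796 with at least 10 counts and 0.607 to 0.804 without single libraries. Lists that passed, 14, 13 and 13 in that order, fell to 4, 5 and 0 with an estimated correlation, and in the direct comparison ran from 5 to 17 without single libraries.

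Alternatives added after seeing the data combined the replicate block with a further choice. In the same order they gave 1393, 703 and 33 genes with RLE normalization, 1392, 765 and 186 with DESeq2, 1304, 646 and 29 with limma-voom, 1907, 1120 and 289 without a filter, and 1209, 586 and 29 with thinned counts. Without replicate set 1, 2 or 3 the block gave 1262, 822 and 806 genes for RA, 569, 376 and 408 for 4-oxo-RA, and 102, 23 and 9 in the direct comparison, with fewer samples.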

Other observations

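All tests on homeologs and replicate sets in this part were chosen only after the main results were seen. Most homeologs that were both called moved alike in direction, while many pairs had only 1 copy past the threshold. Of 3512 pairs with both copies tested, 137 had at least 1 copy called for RA, of which 33 had both called, all 33 in the same direction, 59 only L and 45 only S. For 4-oxo-RA the values were 65, 17, 17, 29 and 19. With the replicate block 130 pairs had both copies called for RA, 122 in the same direction, and 64 for 4-oxo-RA, 61 in the same direction. The L and S responses of all pairs correlated with r = 0.520 for RA and 0.428 for 4-oxo-RA. The difference between L and S responses, tested by itself with limma on log2 CPM, passed for 27 pairs with RA and 3 with 4-oxo-RA, and for 61 and 1 with the replicate block. The segmentation gene mespa differed with RA (edgeR values of 2.93 for L and 0.08 for S, limma adjusted p = 0.0120), as did the neurofilament gene nefm (1.07 and −1.53, limma adjusted p = 0.00383).

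Replicate numbers marked sets of libraries that differed from one another whatever the treatment. Of 20811 genes 4595 differed between the 3 sets, 1728 of them at least 2-fold, and 35 were absent from at least 1 set while reaching 1 CPM in another.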
